A study of Mus musculus with 18 samples.

How the data were processed

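The deposited tables hold 18 Illumina bead arrays of total RNA from mouse testis, labelled with biotin. Per the submitters' processing notes the arrays were summarised with GenomeStudio 1.7.0. Further steps are not given in the sources used here. Per the file headers the deposited table of unnormalized values gives, for each of 45281 probes and each array, the mean bead intensity, the detection p-value and the number of beads. The deposited intensity values are on a linear scale, and nothing in them shows background subtraction. The deposited detection p-value moves in steps of 1 over 936 negative control probes. A second deposited table holds the authors' processed intensity values. They share nearly the same distribution on all arrays, are linear, and were used only as an alternative, since their normalization method is not given in the sources used here. Their array medians lay between 61.6 and 61.7, and each of the 18 columns had its highest rank correlation with the same array's unnormalized values. The lowest of these correlations rounded to 1. The processed values thus kept the order of the unnormalized values on a nearly common distribution, as quantile normalization does. This alternative is therefore not independent of the normalization used here.

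Array groups were taken from the genotype in the labels. No pair of arrays held identical values. The median number of beads per probe was 40 to 43, and the detected probes per array are given with the results. Intensities were background-corrected with the normexp model of limma 3.58.1 in R 4.3.3, with the background inferred from the detection p-values and an offset of 16, and then quantile normalized and taken to log2. Probes were kept if detected at p under 0.01 on at least 4 arrays. Of all probes, 34885 have 1 gene symbol, 18 have several and 10378 have none here; symbols of 34807 probes were updated through their gene identifier with the reference gene table. The brightest probe stood for a gene, which left 10798 genes. Of these, 3748 had more than 1 probe past the filter, and in 308 of them probes were called in opposite directions between Lhr null and wild type.

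A linear model with 4 group means was fitted to all 18 arrays with limma and moderated with eBayes, so that all groups share 1 estimate of the spread. The contrasts were Lhr null, Fshr mutant and double mutant against wild type, double mutant against Lhr null and against Fshr mutant, and the interaction. Adjusted p-values are Benjamini-Hochberg values, called at 0.05. Differences are log2 with the moderated standard error, and folds are on the intensity scale after the offset, which understates changes of dim probes. Where a gene was detected on no array of a group, the fold is given as a lower bound: the mean of the bright group against the mean, over the dim arrays, of the higher of the lowest detected signal and the probe's own. The 25 gene lists were tested with camera at a preset correlation of 0.01, with adjustment over all lists with at least 3 tested genes and all 6 contrasts, and again with an estimated correlation. With all 18 arrays no list call held with an estimated correlation. Of the tested list members, 15 stand in more than 1 list. Each list was also counted by member, over all genes and adjusted over the list alone. The list score of an array is the mean log2 level of the members minus its wild type mean.

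The recovery of a gene is the difference of the double mutant from Lhr null over that of wild type from Lhr null. Genes named in the text come from a rule: per contrast the 8 highest and 8 lowest called genes whose groups do not overlap, up to 4 called members of each list, Fshr and Lhcgr, and a fixed set of testis genes. Values are printed for part of them. Of the fixed set, Hsd3b6, Amh, Inhbb and Sycp3 were not analysed here because no named probe of theirs passed the detection filter. The groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined.

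The model was tested on simulated data for 10798 genes with the residual spread of the arrays, in 5 simulations per comparison with 335 genes changed at a fold of 1.5, 335 at 2 and 330 at 4 in all. At a fold of 2 it recovered 87.8% for Lhr null against wild type, 87.5% for Fshr mutant against wild type, 91.6% for double mutant against Lhr null, 87.5% for double mutant against Fshr mutant, 88.7% for double mutant against wild type and 67.8% for the interaction. False calls made up 5.14%, 6.26%, 6.28%, 5.50%, 4.84% and 5.10% of all calls in that order. At a fold of 1.5 the share recovered was 52.8% for Fshr mutant against wild type. The share recovered depends on how many genes change, since the Benjamini-Hochberg cutoff does. The real comparisons differ from this setting, with 0 genes called for Fshr mutant and 7689 for Lhr null against wild type. The simulated shares are thus not the power of those comparisons. A planted list of 20 genes shifted by 0.5 log2 was found in 20 of 20 simulations, and a planted recovery of 0.5 was estimated as 0.502. The simulated genes varied independently, so the planted list does not bear on lists whose members vary together. The estimated correlation was 0.65 for the elongating and 0.47 for the round spermatid list. Alternatives changed the background correction, normalization, detection filter, probe rule, model, threshold and arrays. No genome build is named in the files, so no coordinates are given.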

Results

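Transcripts were measured in whole testis of 12-week-old mice with Illumina bead arrays, 1 array per sample, on a cross of the FVB/N and C57/BL6 strains. The 18 arrays fell into 4 groups: 4 wild type, 4 Fshr mutant, 5 Lhr null and 5 carrying both the Fshr mutation and the Lhr null, called the double mutant below. Fshr encodes the follicle stimulating hormone receptor of Sertoli cells, and Lhr (Lhcgr) the luteinizing hormone receptor of Leydig cells. The column headers of the deposited table write the mutant allele as Fshr-CAM, and neither they nor the labels say what the mutation does. The series title names the question: which testis transcripts depend on each hormone and how the 2 pathways act on each other. Between 15482 and 18950 of 45281 probes were detected per array, and 10798 genes were tested. The number of arrays limits the precision of every value. The labels do not state that each array came from a separate animal, so the p-values measure the spread between these samples.

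Fshr itself was examined first, since it checks the labels. Its brightest probe had a log2 intensity of 5.58 ± 0.30 (SD, n = 4) in wild type and 8.59 ± 0.14 (SD, n = 4) in Fshr mutant arrays. It was 7.93 ± 0.31 (SD, n = 5) in Lhr null and 8.17 ± 1.42 (SD, n = 5) in double mutant arrays. The large spread of the double mutant came from 1 array: the array labelled Fshr mutant/Lhr null replicate 2 had Fshr at 5.68, inside the wild type range of 5.16 to 5.85, while the other 4 had a mean of 8.79. This array is called "the array labelled Fshr mutant/Lhr null replicate 2" throughout, and the gene counts and part of the gene and list values of each double mutant comparison are also given without it, an alternative chosen after its Fshr level was seen. The Fshr probes differed from each other. The probe ILMN_2932141 was at 8.20 ± 0.28 (SD, n = 5) in Lhr null and at 5.98 ± 0.29 (SD, n = 4), 5.62 ± 0.22 (SD, n = 4) and 5.71 ± 0.32 (SD, n = 5) in wild type, Fshr mutant and double mutant arrays. The probe ILMN_2736929 was not detected on any array. Whether any of them lies in the altered part of the gene is not given in the sources used here. By the brightest probe Fshr was 5.13-fold higher in Lhr null than in wild type (2.36 ± 0.47, SE), where wild type had it detected on 3 of 4 arrays. Between double mutant and Lhr null it differed by 0.23 ± 0.45 (SE, adjusted p = 0.649), by 0.85 without the array labelled Fshr mutant/Lhr null replicate 2 (adjusted p = 4.52e-04), and by -1.13 with the mean of its probes (adjusted p = 6.65e-04). The probe ILMN_2932141 alone differed by -2.49 ± 0.17 (SE, limma adjusted p = 1.71e-09) in this comparison. Lhcgr has no named probe here, so the Lhr null label was not checked on its own transcript.

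**Figure D1:**
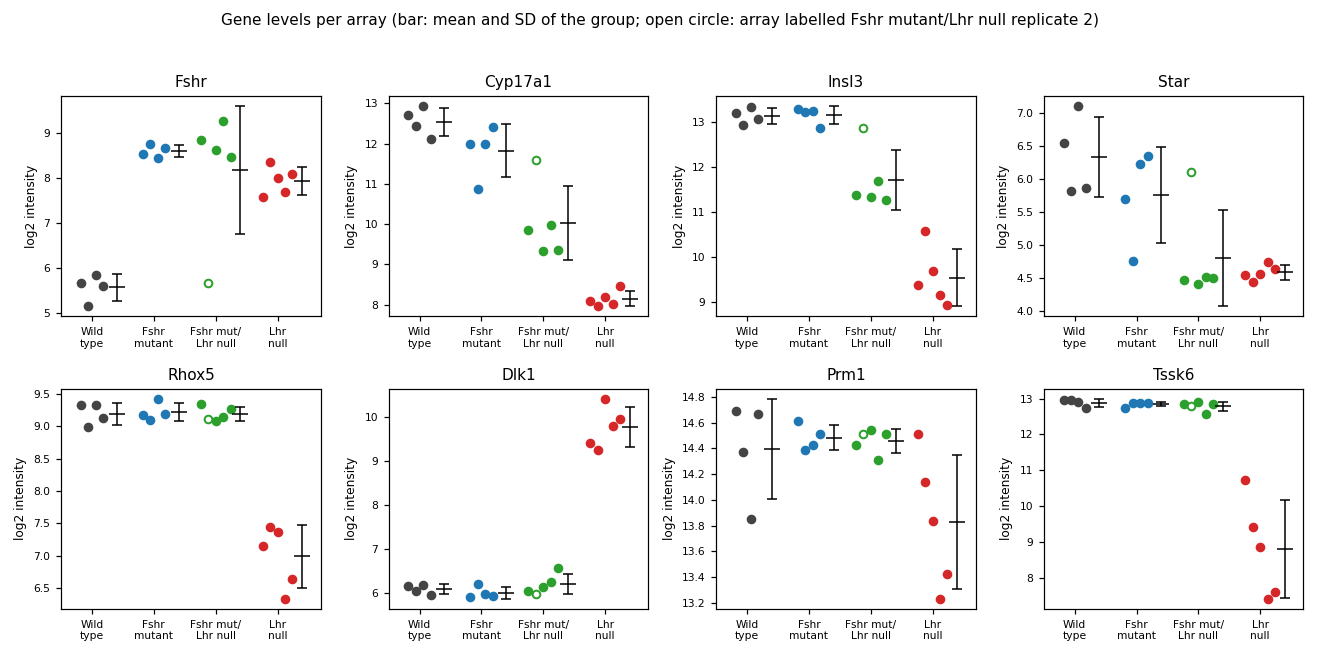
Log2 intensity of 8 genes on each of the 18 arrays, by group; points are arrays, and the bar beside each group is its mean with SD. The open circle, the array labelled Fshr mutant/Lhr null replicate 2, lies at 5.68 for Fshr among the wild type arrays (5.16 to 5.85), while Tssk6 is at 7.41 to 10.73 in Lhr null and at 12.58 or above elsewhere.

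Lhr null testes had lower levels of spermatid and Leydig cell transcripts than wild type and higher levels of Sertoli cell and spermatogonial transcripts. The median log2 difference was 0.94 for Sertoli, 0.77 for spermatogonial and 0.79 for ribosomal and housekeeping genes. A rise of this size was thus not confined to genes of these cell types. Of 38 tested genes of elongating spermatids, 37 were lower and 0 higher, with a median log2 difference of -2.20. Tssk6, a kinase of spermatids, differed by -4.09 ± 0.44 (SE) and Fscn3, an actin-bundling protein of spermatid heads that was detected on 3 of 5 Lhr null arrays, by -3.81 ± 0.35 (SE). Tnp1 and Prm1, which package sperm chromatin, differed less, by -1.27 ± 0.22 (SE) and -0.57 ± 0.21 (SE), and Prm1 lost its call with cyclic loess (-0.20). Prm1 was bright, at 13.85 to 14.69 in wild type. Quantile normalization gave it the same value of 14.51 on Fshr mutant replicate 4, Lhr null replicate 1, the array labelled Fshr mutant/Lhr null replicate 2 and Fshr mutant/Lhr null replicate 5. A shared value shows only an equal rank, so the size of its difference is uncertain in either direction. Of 33 genes of round spermatids and the acrosome, 29 were lower and 1 higher, among them Theg (-2.23 ± 0.18, SE) and Acrv1 (-1.23 ± 0.18, SE). The camera adjusted p was 7.04e-14 for the elongating and 1.70e-09 for the round spermatid list, and adjusted p = 0.473 for both with an estimated correlation. Adjusted over the list alone, 37 elongating and 30 round spermatid genes were lower.

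Leydig cell genes were among those with the largest decreases in Lhr null testes. Cyp17a1, the steroid 17-alpha-hydroxylase needed to make androgens, was at 12.55 ± 0.35 (SD, n = 4) in wild type and 8.15 ± 0.19 (SD, n = 5) in Lhr null, 21.1-fold lower. Insl3, a peptide hormone of Leydig cells, was 12.0-fold lower and Cyp11a1, which starts steroid synthesis from cholesterol, 2.76-fold lower. Hsd17b3, which makes testosterone, and Star, which carries cholesterol into mitochondria, were detected on 0 Lhr null arrays, and were at least 4.49-fold and at least 2.09-fold lower. Of 8 steroidogenic genes, 5 were lower and 3 higher, also adjusted over the list alone, and camera made no call (adjusted p = 0.309, and adjusted p = 0.762 with an estimated correlation). Of 12 other Leydig markers, 8 were lower and 2 higher, also adjusted over the list alone, with a median of -2.05 (camera adjusted p = 0.0399, and adjusted p = 0.597 with an estimated correlation). The kallikrein Klk1b21 differed by -4.98 ± 0.64 (SE) and was detected on 2 of 5 Lhr null arrays, and Klk1b27, detected on 0 Lhr null arrays, was at least 16.6-fold lower. The only tested member of the immature or fetal Leydig list, Hsd17b1, was higher by 0.68 ± 0.16 (SE). Its level was 7.48 on Lhr null replicate 2, against a mean of 6.57 on the other Lhr null arrays. This 1 gene does not tell whether genes of immature or fetal Leydig cells rose.

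Sertoli cell markers were mostly higher in Lhr null testes, while androgen-dependent Sertoli genes were lower or not past the test. Of 25 Sertoli markers, 16 were higher and 2 lower, also adjusted over the list alone, with a median of 0.94 (camera adjusted p = 0.0372, and adjusted p = 0.507 with an estimated correlation). Shbg, the androgen-binding protein, was 4.87-fold and Inha, a subunit of inhibin, 3.71-fold higher. Ptgds, a prostaglandin synthase in the same list, was 15.2-fold lower and detected on 2 of 5 Lhr null arrays. Of 11 androgen-dependent Sertoli genes, 4 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.107). Rhox5, a homeobox gene that androgen induces in Sertoli cells, differed by -2.21 ± 0.18 (SE) and Defb45 by -2.13 ± 0.21 (SE), while Eppin (-0.21 ± 0.13, SE) did not pass, though it did with median scaling and cyclic loess (-0.36 in both). Of 15 spermatogonial genes, 13 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.0486, and adjusted p = 0.473 with an estimated correlation). Their median was 0.77, beside 0.79 for ribosomal and housekeeping genes. Dazl, an RNA-binding protein of germ cells, was 3.02-fold and Rhox13 2.61-fold higher. Stra8, which retinoic acid induces before meiosis, was detected on 0 wild type arrays and was at least 1.26-fold higher.

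Among the remaining lists, 14 of 27 spermatocyte genes were higher and 5 lower, with Tex101 at 1.79 ± 0.12 (SE) and Meiob at 1.46 ± 0.13 (SE). Mitotic genes were higher for 11 of 19 and lower for 1, with Mcm5, a subunit of the replication helicase, 3.10-fold higher. Cholesterol synthesis genes were lower for 6 of 15 and higher for 3, with Insig1 at -2.15 ± 0.17 (SE) and Cyp51 at -2.02 ± 0.23 (SE). Smooth muscle and myoid genes were higher for 6 of 9 and lower for 1 (Acta2, 2.37-fold higher), and matrix genes were higher for 11 of 16 and lower for 2 (Mgp, 3.47-fold higher). Macrophage genes were lower for 6 of 18 and higher for 2 (Aif1, 4.88-fold lower). Higher and lower members numbered 10 and 6 of 21 FSH and cAMP response genes, 8 and 3 of 15 junction genes, and 2 and 2 of 11 endothelial genes. They numbered 6 and 0 of 7 retinoic acid genes, 4 and 1 of 10 interferon genes, 6 and 3 of 12 stress genes, and 9 and 1 of 11 ribosomal and housekeeping genes (median 0.79, camera adjusted p = 0.118). They numbered 0 and 2 of 3 lymphocyte genes, 0 and 1 of 4 red blood cell genes, and 0 and 2 of 3 epididymal genes. Camera called none of the lists in this paragraph. Of all 10798 tested genes 71.2% were called in this comparison, 4770 higher and 2919 lower. List counts near these shares are therefore not particular to the list. Actb, a common loading control, was 1.91-fold lower, and was not called with the mean of its probes (-0.20).

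In all, 7689 of 10798 genes passed an adjusted p of 0.05 in limma between Lhr null and wild type, 4770 higher and 2919 lower, and 2476 of them had an absolute log2 difference of at least 1 (1018 higher, 1458 lower). The genes farthest apart included Dlk1 (3.68 ± 0.18, SE), a membrane protein of immature cells, Col18a1 (2.87 ± 0.17, SE) and Hs6st2 (2.84 ± 0.19, SE) upward, and Lcn2 (-6.50 ± 0.44, SE), Car2 (-4.44 ± 0.37, SE) and Spata32 (-4.35 ± 0.40, SE) downward. Lcn2 was detected on 2 and Car2 on 4 of 5 Lhr null arrays, and Hs6st2 on 2 of 4 wild type arrays. The median of all genes lay at 0.21 and was 0.02 with cyclic loess, where 50.6% of calls were higher against 62.0%.

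Fshr mutant testes did not differ from wild type in any tested gene at this threshold: limma called 0 genes, 437 genes (4.05%) had an unadjusted p under 0.05, and the smallest adjusted p was 0.0564, shared by Fshr and Gtf2ird2. By its brightest probe Fshr was 3.02 ± 0.50 (SE) higher on the log2 scale, 8.10-fold, on 4 of 4 mutant arrays. The probe ILMN_2932141 differed by -0.35 ± 0.19 (SE) and was not called. Without the array labelled Fshr mutant/Lhr null replicate 2, whose spread enters the shared variance, 3 genes were called, all higher: Fshr (adjusted p = 1.65e-07), Gtf2ird2 and Slc6a7, with Slc6a7 named after their values were seen. The count was 6 without Lhr null replicate 1, 4 and 2 without Fshr mutant/Lhr null replicate 5 or 4, 1 without wild type replicate 1 or Fshr mutant replicate 4, and 6 with array weights. No member of any list was called over all genes. Adjusted over the list alone, Fshr passed in the receptor and Sertoli lists. The steroidogenic list had a median of -0.31 with 0 of 8 members called (camera adjusted p = 0.00985, and adjusted p = 0.506 with an estimated correlation). Its score ran from -0.79 to 0.01 over the Fshr mutant arrays and from -0.20 to 0.34 in wild type. Fshr mutant replicate 2 had Cyp17a1 at 10.87 and Star at 4.76, against 11.99 to 12.41 and 5.69 to 6.35 on the other Fshr mutant arrays.

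In the double mutant, with the array labelled Fshr mutant/Lhr null replicate 2 included, spermatid transcripts were higher than in Lhr null, and Sertoli and spermatogonial transcripts were lower. Of 38 elongating spermatid genes, 37 were higher and 0 lower (median 2.05), and of 33 round spermatid genes 29 were higher and 1 lower (median 1.19), with the same counts adjusted over the list alone. The camera adjusted p was 1.42e-13 and 1.70e-09, and adjusted p = 0.473 for both with an estimated correlation. Fscn3 was higher by 3.81 ± 0.33 (SE), and Tssk6 was 15.9-fold, Theg 5.09-fold, Tnp1 2.41-fold, Acrv1 2.28-fold and Prm1 1.55-fold higher. Bpifa3 (4.24 ± 0.40, SE), Paqr5 (4.13 ± 0.37, SE), Car2 (4.45 ± 0.35, SE) and Lcn2 (5.13 ± 0.41, SE) were among the genes farthest apart upward. Of 25 Sertoli markers, 18 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 0.0285, adjusted p = 0.506 with an estimated correlation, and 0.0786 without normalization between arrays), with Shbg 5.76-fold and Inha 2.88-fold lower and Ptgds 6.43-fold higher. Of 15 spermatogonial genes, 12 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 0.0399, and adjusted p = 0.473 with an estimated correlation). Ribosomal and housekeeping genes were lower for 9 of 11 and higher for 1 (median -0.70, camera adjusted p = 0.118). The medians of the Sertoli and spermatogonial lists were -1.16 and -0.99, so a decrease was not confined to genes of these cell types. Dazl was 3.36-fold and Tex101 3.05-fold lower, and Crabp1, detected on 0 double mutant arrays, was at least 1.97-fold lower. Dlk1 (-3.57 ± 0.17, SE) and Col18a1 (-2.80 ± 0.16, SE) were lower. Of 11 androgen-dependent Sertoli genes, 6 were higher and 1 lower, including Rhox5 (2.20 ± 0.17, SE) and Eppin (0.31 ± 0.12, SE, not called without normalization between arrays). Without the array labelled Fshr mutant/Lhr null replicate 2, 37 elongating and 29 round spermatid genes were higher, 17 Sertoli, 12 spermatogonial and 8 ribosomal and housekeeping genes were lower, and the differences of Lcn2, Tssk6, Shbg and Ptgds were 4.66, 3.99, -2.48 and 2.48.

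Steroidogenic genes were called in both directions in this comparison. Of 8, 1 was higher and 3 lower, also adjusted over the list alone, with Cyp17a1 3.67-fold higher and Cyb5a 2.66-fold lower. Cyp11a1 (0.37 ± 0.24, SE) did not pass, and was called with cyclic loess (0.57). Hsd17b3 and Star were detected on 0 Lhr null arrays and on 1 of 5 double mutant arrays, the array labelled Fshr mutant/Lhr null replicate 2, so no difference is given. Neither passed (adjusted p = 0.0783 and 0.570), though Hsd17b3 did with median scaling and with cyclic loess. Without that array Hsd17b3 and Star were detected in neither group, Cyp11a1 differed by 0.17 and did not pass, and Cyp17a1 and Insl3 differed by 1.48 and 1.87. Of 12 other Leydig markers, 7 were higher and 4 lower, also adjusted over the list alone, with Insl3 4.48-fold and Klk1b21 7.22-fold higher. Neither Leydig list was called by camera (adjusted p = 0.974 and 0.346). In all, limma called 8015 genes, 3160 higher and 4855 lower, and 7811 without the array labelled Fshr mutant/Lhr null replicate 2, of which 7723 were shared. Without normalization between arrays, 27.9% of calls were higher against 39.4%.

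Of the genes called in Lhr null against wild type, 6987 were called the opposite way between the double mutant and Lhr null: 2685 lower then higher, and 4302 higher then lower. Both comparisons share the Lhr null arrays. Independent lists of these sizes would share 854 and 2145. Unchanged groups simulated 100 times gave at most 1 such gene, but they hold no effects, so that value is no measure of the overlap between lists of these sizes. With the Lhr null arrays divided between the comparisons in 20 ways, the overlap held 5832 to 6426 genes. Over 2476 genes at an absolute log2 difference of at least 1, the double mutant mean lay at a median of 0.983 of the way from Lhr null (0) to wild type (1), with 0.976 to 0.995 over the same divisions and 0.978 without the array labelled Fshr mutant/Lhr null replicate 2. The median was 0.976 over 33 elongating spermatid genes and 1.03 over 21 round spermatid genes. It was 0.251 over 5 steroidogenic genes and 0.550 over 9 other Leydig markers, and 0.115 and 0.448 without that array. Of the 5 steroidogenic genes, Hsd17b3 and Star were detected on 0 Lhr null arrays and, without that array, on 0 double mutant arrays. Among the other Leydig markers, Klk1b27 was detected on 0 Lhr null arrays. For such genes the recovery starts from a level not above background, which limits the medians of both Leydig lists.

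**Figure D2:**
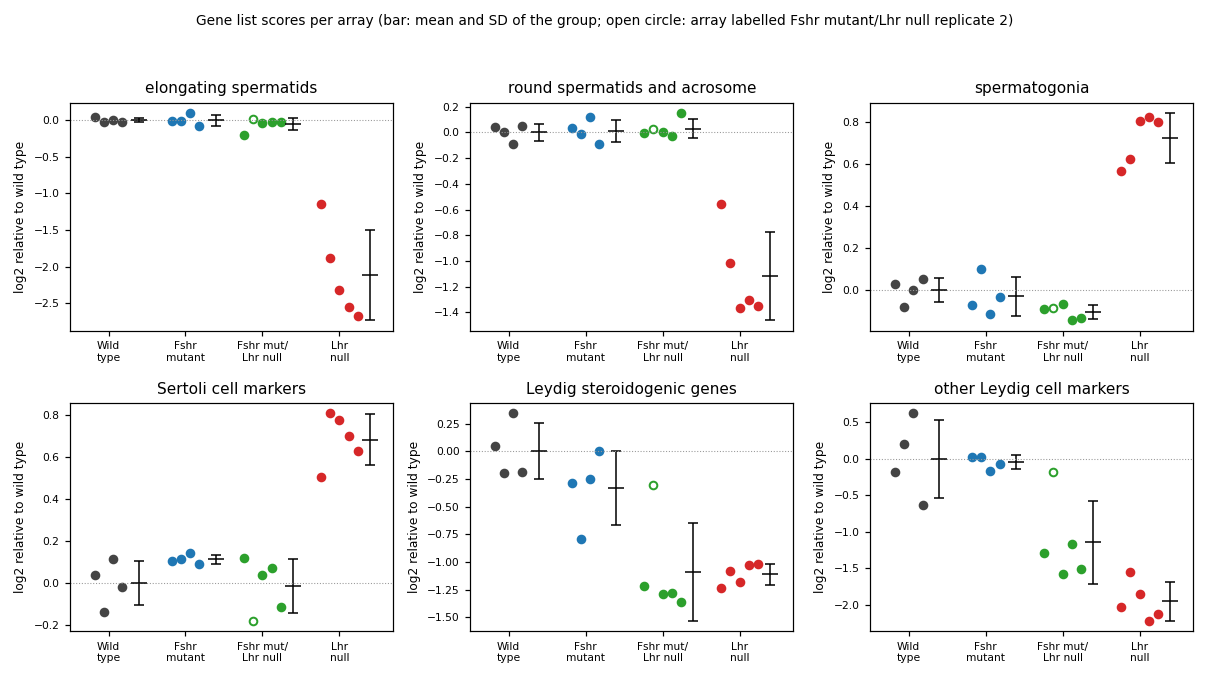
Mean log2 level of the members of 6 gene lists on each array, relative to the wild type mean; points are arrays, and the bar beside each group is its mean with SD. The elongating spermatid score is -2.67 to -1.14 in Lhr null and -0.20 to 0.01 in the double mutant, while the steroidogenic score is -1.23 to -1.02 and -1.36 to -0.31, the last on the array labelled Fshr mutant/Lhr null replicate 2.

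Against wild type, the double mutant had lower Leydig cell transcripts, while no spermatid gene was called. Cyp17a1 was 5.75-fold, Cyp11a1 2.14-fold and Insl3 2.69-fold lower. Hsd17b3 (-2.27 ± 0.38, SE) and Star (-1.54 ± 0.36, SE) were lower too. Each was detected on 1 of 5 double mutant arrays, the array labelled Fshr mutant/Lhr null replicate 2, so these differences rest mostly on levels not above background. Of 8 steroidogenic genes, 4 were lower and 0 higher (6 lower adjusted over the list alone), with a camera adjusted p of 2.75e-08, and adjusted p = 0.473 with an estimated correlation. Of 12 other Leydig markers, 4 were lower and 0 higher (9 lower and 1 higher adjusted over the list alone), with a camera adjusted p of 1.88e-07, and adjusted p = 0.473 with an estimated correlation. Among them were Ces1d (3.59-fold lower), Aldh1a1 (2.71-fold lower) and Fabp3 (2.37-fold lower). Of 15 cholesterol synthesis genes, 2 were lower (3 adjusted over the list alone): Msmo1 by -1.25 ± 0.24 (SE), and Dhcr7, detected on 0 double mutant arrays and at least 1.41-fold lower (camera adjusted p = 0.0152, and adjusted p = 0.473 with an estimated correlation). The junction list was called lower with 0 of 15 members called (median -0.20, camera adjusted p = 0.0496, adjusted p = 0.473 with an estimated correlation, 0.155 with median scaling, and 0.0951 without the array labelled Fshr mutant/Lhr null replicate 2). Of 38 elongating and 33 round spermatid genes 0 were called, also adjusted over the list alone, with medians of -0.05 and 0.06. The differences of Acrv1, Prm1 and Tnp1 were -0.04 ± 0.18 (SE), 0.07 ± 0.21 (SE) and 0.00 ± 0.22 (SE), and those of Rhox5 and Eppin 0.00 ± 0.18 (SE) and 0.11 ± 0.13 (SE).

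In all, 138 genes were called between the double mutant and wild type, 47 higher and 91 lower. The genes farthest apart downward included Ass1 (-2.65 ± 0.48, SE), an enzyme of arginine synthesis detected on 2 of 5 double mutant arrays, Nat8 (-1.56 ± 0.31, SE), Akr1cl (-1.51 ± 0.24, SE) and Pgrmc1 (-1.45 ± 0.29, SE), and Mrap, detected on 0 double mutant arrays and at least 2.07-fold lower. Ptgds was 2.36-fold lower, and the matrix proteoglycan Dcn differed by -0.58 ± 0.13 (SE). Upward were Fshr (6.02-fold by its brightest probe), Gtf2ird2 (3.69-fold), Tmem198 (2.16-fold), Antxr2 (2.11-fold), Rxfp2 (2.01-fold), the receptor of Insl3, and ND5 (1.76-fold), a mitochondrial gene. The Fshr probe ILMN_2932141 differed by -0.27 ± 0.18 (SE) and was not called. Without the array labelled Fshr mutant/Lhr null replicate 2, 181 genes were called, 34 higher and 147 lower, of which 113 were shared, and Cyp17a1 differed by -2.91, Cyp11a1 by -1.30, Insl3 by -1.71, Ass1, then detected on 1 of 4 double mutant arrays, by -3.22 and Fshr by 3.21. Hsd17b3 and Star were then detected on 0 double mutant arrays and still called lower. Then 4 of 8 steroidogenic genes and 8 of 12 other Leydig markers were lower, with an adjusted p of 0.0465 and 0.0890 with an estimated correlation. The count fell to 48, 75 and 6 without wild type replicate 1, 2 or 3, and to 48, 15 and 12 without Fshr mutant/Lhr null replicate 1, 3 or 5. Star, Mrap and Dhcr7 lost their call with median scaling, and Tmem198, Antxr2, Rxfp2 and ND5 without normalization between arrays. Without normalization between arrays, 1.33% of calls were higher against 34.1%. Of the genes called in Lhr null against wild type, 69 were called the same way here, 45 lower and 24 higher, where independent lists would share 24.6 and 20.8, and dividing the wild type arrays in 6 ways gave 0 to 27. Both comparisons share the wild type arrays, so independent lists are no fair reference. The divided fits called only 0 to 83 genes between double mutant and wild type, so they do not decide whether the calls are shared. Unchanged groups simulated 100 times shared 0, which, with no effects in them, does not bear on these 69. The observed overlap was 27, 29 and 3 without wild type replicate 1, 2 or 3, 43 without Fshr mutant replicate 1, and 22, 9 and 8 without Fshr mutant/Lhr null replicate 1, 3 or 5.

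The double mutant and the Fshr mutant differed in 3 genes: Ptgds (2.91-fold lower), Cldn10 (3.44-fold lower), a tight junction protein detected on 1 of 5 double mutant arrays, and Dclk3 (1.79-fold higher). The Leydig lists were lower as groups, with a median of -0.46 for the steroidogenic genes (camera adjusted p = 2.37e-07, and adjusted p = 0.473 with an estimated correlation) and of -1.16 for the other markers (camera adjusted p = 4.71e-12, and adjusted p = 0.367 with an estimated correlation). No member of either was called over all genes, and 4 of 8 and 8 of 12 were lower adjusted over the list alone. The cholesterol synthesis list had a median of -0.11 with 0 of 15 called, and 1 lower adjusted over the list alone (camera adjusted p = 0.0399, and adjusted p = 0.473 with an estimated correlation). Without the array labelled Fshr mutant/Lhr null replicate 2, 57 genes were called, 1 higher and 56 lower, including 2 steroidogenic genes and 5 other Leydig markers. Both Leydig lists then had an adjusted p of 0.0465 with an estimated correlation. At an unadjusted p under 0.05 there were 683 genes with all arrays. The count of called genes was 0 without Fshr mutant replicate 1 or 2 or Fshr mutant/Lhr null replicate 1, 1 without wild type replicate 2 or 4 or Lhr null replicate 3, 4 or 5, and 8 without wild type replicate 3. With all arrays it was 77 with array weights and 0 with no detection filter.

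The effect of the Fshr mutation differed between the Lhr null and the normal Lhr background in 6488 genes by the interaction term, 2503 with a more positive and 3985 with a more negative effect in the Lhr null background, with the array labelled Fshr mutant/Lhr null replicate 2 included. The interaction was 5.36 ± 0.62 (SE) for Lcn2, 4.45 ± 0.53 (SE) for Car2, 4.03 ± 0.62 (SE) for Tssk6, 3.71 ± 0.50 (SE) for Fscn3 and 2.17 ± 0.25 (SE) for Rhox5. It was also positive for Cyp17a1 (2.60 ± 0.52, SE) and Insl3 (2.14 ± 0.44, SE). It was negative for Me1 (-3.52 ± 1.20, SE), Dlk1 (-3.48 ± 0.26, SE), Col18a1 (-3.03 ± 0.24, SE), Fshr (-2.79 ± 0.67, SE), Shbg (-2.49 ± 0.21, SE) and Inha (-1.90 ± 0.19, SE). By list, 34 of 38 elongating and 29 of 33 round spermatid genes had a positive interaction, and 15 of 25 Sertoli and 12 of 15 spermatogonial genes a negative one, with the same counts adjusted over the list alone. Without the array labelled Fshr mutant/Lhr null replicate 2 the count was 6303, of which 6199 were shared, and the interaction was -2.17 for Fshr, 4.89 for Lcn2, -3.06 for Me1, 2.21 for Cyp17a1 and 1.85 for Insl3. It was then positive for 33 elongating and 29 round spermatid genes, and negative for 14 Sertoli and 12 spermatogonial genes. With cyclic loess 50.3% of calls were positive against 38.6%, and without normalization between arrays 4254 genes were called.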

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

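The tests of the 3 patterns below were chosen after the patterns were seen, except the test without normalization between arrays. The counts over other splits of the samples were planned.

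The array labelled Fshr mutant/Lhr null replicate 2 stood apart from its group in Fshr (5.68, mean of the other 4 at 8.79), Ass1 (8.51), Ces1d (9.41), Cyp17a1 (11.60), Fabp3 (10.82), Hsd17b3 (7.03), Insl3 (12.85), Lcn2 (12.25), Star (6.11), the steroidogenic list score (-0.31) and the housekeeping list score (-0.13). An exchange with a wild type array of this series is argued against, since the highest wild type Fshr value was 5.85 and no partner is out of place, and so is a dim array, with 16526 detected probes inside the range of the others. A wild type sample under a double mutant label may account for the Fshr level. Its position was taken over 182 genes called between double mutant and wild type in a fit without it, on values normalized with all 18 arrays. The median position from wild type (0) to the other double mutant arrays (1) was 0.381, above the 0.3 set for that explanation and below the 0.7 set against it. Wild type arrays left out in the same way had -0.403 to 0.333 and double mutant arrays 0.784 to 1.11. Wild type replicate 4, at 0.333, also lay above 0.3, so missing that limit does not count against the explanation. These values leave the label open, and no biological explanation was tested.

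Lhr null replicate 1 had spermatid genes closer to wild type than the other Lhr null arrays, with an elongating spermatid score of -1.14 against -1.88 to -2.67. Wild type testis RNA mixed into the sample would give 1 share for all genes. The share was 0.346 from 54 spermatid genes and -0.00510 from 12 Leydig genes, and this gap of 0.351 exceeded that of each other Lhr null array (-0.141 to 0.0266), which argues against mixing. A double mutant sample under this label is argued against by its second Fshr probe at 7.90, since that probe averaged 5.71 in the double mutant. Variation between Lhr null animals stays open as untested.

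The array medians of the Sertoli, myoid and matrix lists were 1.01, 0.69 and 0.59 above wild type in Lhr null, of which camera called the Sertoli list alone, while those of the endothelial, macrophage and other Leydig lists were at 0.02, -0.34 and -2.13. A lower share alone would raise every other cell type alike, but the list medians of the Sertoli and the other Leydig markers differed by 3.14 ± 0.243 (SE) in their shift from wild type, and those of the Sertoli and macrophage lists by 1.36 ± 0.223 (SE) with the Leydig list set aside. These were the highest and lowest lists, picked from the same data, and the SE ignores that both were scored on the same arrays. Ribosomal and housekeeping genes, not among these lists, had a median log2 difference of 0.79. The normalization step alone is argued against by the 13 of 16 Sertoli markers that were still called higher without normalization between arrays. A relative rise already present in the unnormalized intensities would pass this test too, so the test does not bear on it. A lower germ cell share together with changes within the other cell types stays open, as a hypothesis from the same data.

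For Lhr null against wild type (7689, highest of the other splits 7249), 1 of 100 splits, the real one, gave a count as large. The same held for double mutant against Lhr null (8015, highest 5767). This is the lowest share the test can give, and it argues against chance as the source of both counts. It also held for double mutant against wild type (138, highest 132), but the margin was small. That count also varied widely without 1 array, and its smallest adjusted p in limma was 0.0108, so chance is not excluded. For the interaction (6488, highest 6361) it held as well, but labels moved only within each Lhr background. Such splits mostly retest double mutant against Lhr null and do not test the interaction by itself. The overlaps were 6987 against at most 4538 and 69 against at most 7, but since the other splits called a median of 0 genes, this adds nothing to the counts themselves and does not bear on whether the calls are shared. Why some other splits gave counts near the real ones was not tested. A split that exchanges few arrays keeps most of the real grouping. For the Fshr mutant against wild type the splits decide nothing, since with a real count of 0 all 35 of 35 splits are as large by construction, and the highest other gave 2. Chance is also not excluded for the double mutant against the Fshr mutant, where 6 of 100 splits gave at least 3 and the highest gave 74. Why that split gave 74 was not tested.

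Of 255 groups of values examined for an array far from the others, 24 had such an array, where chance gives about 1 in 20, and 11 of the 24 lay on the array labelled Fshr mutant/Lhr null replicate 2. The others were single values. Acrv1 was 12.71 on Fshr mutant/Lhr null replicate 4, Dazl 10.06 on Fshr mutant/Lhr null replicate 1, and Actb 13.15 on wild type replicate 3. Cyp11a1 was 5.43 on Lhr null replicate 3 and Hsd17b1 7.48 on Lhr null replicate 2. Insl3 was 12.85 on Fshr mutant replicate 4 and Tssk6 12.75 on Fshr mutant replicate 1. On Fshr mutant replicate 1 the androgen-dependent Sertoli score was -0.17 and the FSH and cAMP score -0.029. The elongating spermatid score was -0.20 on Fshr mutant/Lhr null replicate 1, the lymphocyte score -0.11 on Fshr mutant/Lhr null replicate 5, the endothelial score 0.45 on Lhr null replicate 2 and the mitotic score 0.50 on Lhr null replicate 1.

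The effect of the Fshr mutation differed between the Lhr backgrounds in 6488 genes by the interaction term, and by camera in the elongating spermatid (adjusted p = 7.04e-14), round spermatid (1.69e-09), Sertoli (0.0152) and spermatogonial (0.0383) lists, each with an adjusted p of 0.473 with an estimated correlation. Among 2950 detected probes with no gene name here, outside the comparisons of genes, 1997 differed between Lhr null and wild type, 1029 higher and 968 lower.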

How the results depend on the processing

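Of the alternatives below, those that drop the array labelled Fshr mutant/Lhr null replicate 2, alone with only the compared groups or with Lhr null replicate 1, were chosen after the data were seen, and all others were planned. Of 2006 values of named genes under alternatives 1884 kept their side of the threshold and, where called, their direction, as did 1876 of 2030 without 1 array, and of 3174 gene list tests 3096 kept their call. The sign turned in 19 and 16 of these values. In 1 of them the value was past the threshold in the alternative, though not in the reported analysis: Fshr between double mutant and Lhr null with the mean of probes (-1.13), where probes with different patterns are averaged. The others were called in neither. At an absolute log2 difference of at least 1, which by construction calls fewer genes, the counts were 2476 for Lhr null against wild type, 2682 for double mutant against Lhr null, 51 for double mutant against wild type, 2557 for the interaction, 2068 for the opposite overlap and 27 for the same-way overlap. At an adjusted p below 0.01, 0 genes were called for double mutant against wild type, against Fshr mutant and in the same-way overlap, where limma gave 1769 genes (wild type) and 683 (Fshr mutant) at an unadjusted p under 0.05. Fshr mutant against wild type gave 2 genes without normalization between arrays, 3 with detection on all arrays of a group, 3 with only the 2 groups, 6 with array weights, and 3 under each alternative chosen after seeing the data. Double mutant against Fshr mutant gave 1 gene with cyclic loess, with only the 2 groups and with trend and robust moderation, 0 with no detection filter, 5 with the mean of probes or every probe, 10 without normalization between arrays, 77 with array weights, and 83 and 64 under the alternatives chosen later. Double mutant against wild type gave 228 with only the 2 groups, 844 with array weights, and 291 and 239 under those chosen later. The same-way overlap was 42 with no detection filter, 361 with array weights, and 128 and 119 under those chosen later. Without normalization between arrays the interaction gave 4254 genes and the median recovery was 0.871. For the values that moved, other than by a stricter threshold or by averaged probes, the cause was not tested.

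Without 1 array at a time the counts were 7271 to 7705 for Lhr null against wild type, 0 to 6 for Fshr mutant against wild type, 7711 to 8029 for double mutant against Lhr null, 0 to 57 against Fshr mutant, 6 to 202 against wild type and 6159 to 6737 for the interaction. The opposite overlap was 6644 to 7073, the same-way overlap 3 to 98 and the recovery 0.977 to 0.997. With the replicate number as a block the counts were 7512, 0, 7990, 1, 21 and 6374 in that order, and the same-way overlap was 13. The arrays gave no clear sign that the numbers pair the samples. Of 25 pairs of arrays with the same number, 5 had a correlation of deviations over 0.1 (-0.317 to 0.215), and 6 of 18 arrays correlated best with their own number. The median correlation was -0.0205 for the same number and -0.000730 for the 96 pairs with different numbers. No chance level was computed, so pairing is not excluded. The median of all genes moved by over 0.1 with cyclic loess, to 0.02, -0.05 and -0.05 for Lhr null against wild type, double mutant against Lhr null and the interaction. Without normalization between arrays it moved to -0.17 for Fshr mutant against wild type, and to -0.44, -0.15 and -0.31 for double mutant against Lhr null, Fshr mutant and wild type. The chip as a block was not run, since the tables used name no chip. Signal near background limits genes such as Hsd17b3 and Star, for which only a lower bound of the fold between wild type and Lhr null can be given, and no fold between double mutant and Lhr null. Over all tested genes, changes simulated at a fold of 1.5 were called for 26.3% in the interaction and for up to 60.3% in the other comparisons. These shares hold for the number of changed genes simulated, not for the number in each real comparison.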

Other observations

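The values in this part were chosen for mention after the results were seen, except the list counts, which were planned. In the double mutant against Lhr null, members of other gene groups were called, though camera called none of these lists. Of all 10798 tested genes 74.2% were called in this comparison, 3160 higher and 4855 lower. List counts near these shares are therefore not particular to the list. Of 7 retinoic acid genes, 7 were lower and 0 higher (median -0.87, camera adjusted p = 0.152). Of 19 mitotic genes 12 were lower and 2 higher (camera adjusted p = 0.186), of 16 matrix genes 11 lower and 2 higher (camera adjusted p = 0.144), and of 15 junction genes 10 lower and 2 higher (camera adjusted p = 0.202). Of 18 macrophage genes 2 were higher and 1 lower (camera adjusted p = 0.346), and of 11 endothelial genes 3 were higher and 3 lower (camera adjusted p = 0.658). The 6 macrophage genes with an absolute log2 difference of at least 1 between Lhr null and wild type had a median recovery of 0.323 (quartiles 0.179 and 0.795), or 0.248 without the array labelled Fshr mutant/Lhr null replicate 2. Over 14 Sertoli markers the median recovery was 0.935, and over 4 matrix genes 1.24, and the difference between lists was not tested. The array labelled Fshr mutant/Lhr null replicate 2 is included in these values except where said.

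Without the array labelled Fshr mutant/Lhr null replicate 2, the 56 genes lower in the double mutant than in the Fshr mutant included, with their log2 differences, Klk1b27 (-2.89), Ass1 (-2.80, detected on 1 of the 4 double mutant arrays), Ces1d (-2.33), Cyp17a1 (-2.18), Ptgds (-1.75) and Insl3 (-1.74). With all arrays only Ptgds of these was called.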
